A study of Homo sapiens with 4 samples.

How the data were processed

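H1 cells at the anterior foregut endoderm stage, exposed to 0 nM, 100 nM, 1 uM or 10 uM retinoic acid, were profiled as 2 single-cell RNA libraries (A and B), each with a hashtag library, which makes 4 GEO samples. Per the labels' protocols, each dose was stained with 1 of 4 hashtag antibodies, equal counts of the doses were pooled, and 9900 cells went into each 10x Genomics 3' library. Sequencing on an Illumina NextSeq gave 57698 and 59121 reads per cell for RNA and 567 and 770 for hashtags, per the same protocols. Per the submitters' processing notes, the authors used Cell Ranger 6.1.2 and Scanpy 1.9.1 with GRCh38 (hg38). Their annotation, their cell filter and whether reads were counted by strand are not given in the sources used here. The deposited matrices, 1 per library and dose, hold raw UMI counts per gene and cell, since all values are whole numbers and totals differ between cells. Several HOX genes overlap antisense genes, so reads of overlapping or paralogous genes remain uncertain. The 4 hashtag features in each matrix were left out (0.551% of counts in A and 0.851% in B).

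Cells with at least 500 detected genes were kept, 6902 of 7378 barcodes, and no other filter was used. Matrices were assigned to library and dose by their names. Counts were summed per library and dose into 8 sums, because cells of one library are not replicates. Over the 8 sums, 134.84 M UMIs fell on 28944 genes, of which 17191 passed edgeR's filterByExpr (minimum count 10). Library A and library B differed by more than counting error at each dose (median chi-square per gene 8.93 to 13.6 on 1 degree of freedom). Genes of 0 counts at a dose get a fold only as a lower bound against 3 counts over the group (0.0746 to 0.110 CPM), and genes of 1 to 3 counts get the ratio with its 95% counting interval.

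The 4 doses were fitted together in edgeR 4.0.16 (TMM, robust quasi-likelihood F test, R 4.3.3) with dose alone in the model, which leaves 4 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and SE is the log2 change over the square root of F. Adjusted p-values are edgeR's unless camera is named. The doses of a letter were pooled into 1 library per the labels, and their log2 ratios of B to A correlate between doses (r 0.727 to 0.782). A fit with the library as a replicate block (3 residual degrees of freedom) was therefore the listed alternative, and it calls 9101 genes at 100 nM against 0 nM where dose alone calls 1766. Of simulated genes changed 1.5-fold (67), 2-fold (67) and 4-fold (66) at 10 uM against 0 nM, dose alone recovered 0%, 10.4% and 57.6%. The library term recovered 92.5%, 100% and 100%, favoured by counts drawn from its fit. False calls were 0 and 6.

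Fixed gene lists (31 over the 5 comparisons, 155 tests adjusted together) were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a correlation of 0.01 between genes, and again with the correlation estimated per list. The lists cover retinoic acid response, synthesis and receptors, HOX genes and their cofactors, regional endoderm, pluripotency, mesoderm, blood, neural and ectoderm genes, signalling pathways and cell state. List counts are given over all genes and adjusted over the list alone, and list medians also with genes of 0 counts at their bound. Genes were named by a rule: 25 anchors always, the largest called changes in the same direction in both libraries with at least 20 CPM at a dose compared (without mitochondrial, ribosomal protein and clone-named genes; 8 per direction against 0 nM, 5 between neighbouring doses), and up to 4 called members per list. Members of lists with 5 or fewer calls in a direction, and the genes named for 10 uM against 1 uM, were also named, after their values were seen. The groups, tests, lists, rule and most alternatives were set before the data were examined. An adjusted p given after a gene or list with a library left out or another setting marks where its call ended. A few named genes are not reported here, while list results count all members.

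Cell cycle phases were called with Scanpy 1.11.5 (score_genes_cell_cycle), and shares of cells with a UMI were counted, after thinning each cell to 5000 UMIs, with 2500 and no thinning as alternatives. Clusters (2000 variable genes, 30 components, 20 neighbours, Leiden resolutions 0.25, 0.5 and 1) served to leave out low-depth and mesoderm-like cells (327, resolution 1) and to count low-depth cells (resolution 0.5). Shares of cell classes were planned but are not reported, since the clusters of 0 nM cells met no fixed naming rule, and the planned selection of an endoderm class could not be run for the same reason. Scrublet called 13 cells in A (0.368%) and 14 in B (0.415%), too few to serve as a doublet filter, so the highest 3% of scores were also removed as an alternative. Other alternatives were DESeq2 1.42.0, its size factors, library totals, no low-count filter or 10 CPM in 2 sums, equal cells (593 per sum), cells under 10% mitochondrial reads with at least 2000 genes, no cycle, mitochondrial and ribosomal genes, a 2-fold minimum, fry, and each sum left out. Coordinates, transcript lengths and GC content come from GENCODE v29, which covered 98.5% of the genes tested. Python tools were anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.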

Results

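Single-cell RNA sequencing was carried out on H1 cells, an established human embryonic stem cell line, that had been differentiated to anterior foregut endoderm, the front part of the gut lining that gives rise to the pharynx and its pouches. Retinoic acid, a vitamin A derivative that patterns the embryo from head to tail, was given from the definitive endoderm stage at 0 nM, 100 nM, 1 uM or 10 uM. The series concerns how human pharyngeal endoderm develops. Cells of the 4 doses were hashtagged and pooled equally into each of 2 RNA libraries, A and B. Each dose thus had 2 sums of counts (n = 2). Of 7378 deposited barcodes, 6902 cells passed the filter. Library A kept 968, 1075, 748 and 738 cells at 0 nM, 100 nM, 1 uM and 10 uM, with 17.68, 19.59, 14.69 and 15.31 M UMIs and median depths of 16569, 14571, 13503 and 15380.0 UMIs per cell. Library B kept 1035, 1050.0, 593 and 695 cells, with 20.6, 20.63, 12.62 and 13.71 M UMIs and median depths of 18048, 16436, 14797 and 14557 UMIs. The labels do not state whether A and B came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Expression is given as TMM-scaled CPM (mean ± SD, n = 2) and changes as log2 change ± SE. A range after a fold is its 95% counting interval, and lists are counted by their measured members.

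Genes fixed beforehand as anchors had their highest means at different doses. DHRS3, a retinaldehyde reductase that retinoic acid induces, stood at 8.10 ± 2.33, 30.7 ± 3.34, 158 ± 28.3 and 233 ± 44.5 CPM at 0 nM, 100 nM, 1 uM and 10 uM. HOXA3, a HOX gene of the pharyngeal arches, stood at 0.668 ± 0.0262, 1.47 ± 0.253, 46.9 ± 13.6 and 95.2 ± 21.6 CPM in the same order. PAX9 and PAX1, paired box factors of the pharyngeal pouches, had their highest means at 100 nM, with 0.645 ± 0.390, 21.5 ± 4.16, 0.104 ± 0.0262 and 0.186 ± 0.152 CPM for PAX9 and 1.44 ± 0.353, 19.9 ± 0.0131, 0.0736 ± 0.0172 and 0.265 ± 0.0416 CPM for PAX1. OTX2, a factor of the anterior endoderm and forebrain, stood at 262 ± 11.6, 141 ± 1.86, 8.65 ± 0.255 and 6.50 ± 0.873 CPM, and GATA4, a factor of the posterior foregut, at 2.81 ± 0.216, 2.45 ± 0.940, 106 ± 8.68 and 119 ± 7.97 CPM. CYP26A1, a retinoic acid-degrading enzyme, stood at 188 ± 82.8, 44.7 ± 13.8, 277 ± 121 and 939.9 ± 429 CPM, and its mean was lower at 100 nM than at 0 nM. EPCAM, an epithelial adhesion protein, stood at 675 ± 254, 539.6 ± 199, 781 ± 277 and 791 ± 268 CPM.

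In GENCODE v29 on GRCh38, protein-coding genes were placed as CYP26A1 (ENSG00000095596; chromosome 10, 93073475 to 93077890), DHRS3 (ENSG00000162496; chromosome 1, 12567910 to 12617731), HOXA3 (ENSG00000105997; chromosome 7, 27106184 to 27152581) and OTX2 (ENSG00000165588; chromosome 14, 56799905 to 56810479). The same annotation gives FGF8 (ENSG00000107831; chromosome 10, 101770130 to 101780369), TBX1 (ENSG00000184058; chromosome 22, 19756703 to 19783593), PAX9 (ENSG00000198807; chromosome 14, 36657568 to 36679715) and PAX1 (ENSG00000125813; chromosome 20, 21705659 to 21718486), and it gives GATA4 (ENSG00000136574; chromosome 8, 11676959 to 11760002) and EPCAM (ENSG00000119888; chromosome 2, 47345158 to 47387601).

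**Figure D1:**
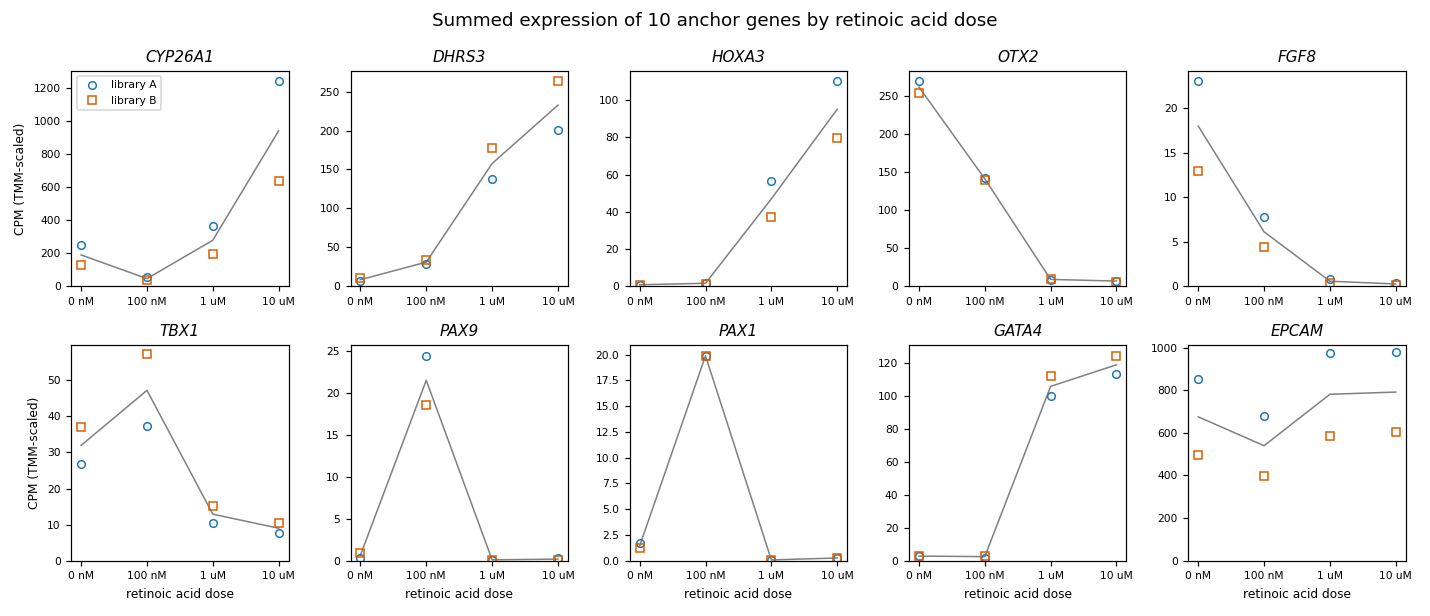
Summed expression of 10 anchor genes (CPM scaled by TMM, vertical axis from 0) against retinoic acid dose, with library A as circles, library B as squares and the mean as a grey line. PAX9 has its highest mean at 100 nM (21.5 CPM), while DHRS3 (233 CPM) and HOXA3 (95.2 CPM) have theirs at 10 uM.

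The comparison of 100 nM with 0 nM asked what the lowest dose changed. PAX9 and PAX1 rose by 5.05 ± 0.44 and 3.78 ± 0.21 (log2, adjusted p = 0.00217 and 0.000978). ROBO2, a Slit receptor, rose from 0.188 ± 0.0411 to 28.6 ± 3.74 CPM (7.20 ± 0.26, adjusted p = 0.000350), and CDH11, a mesenchymal cadherin, rose by 5.81 ± 0.16. HERC3 (5.56 ± 0.39), SMIM32 (4.86 ± 0.21), PCDH17 (4.39 ± 0.31) and ZNF503 (4.33 ± 0.39) were also among the 8 largest rises of the rule for named genes, as was HOXB2 (4.95 ± 0.63, adjusted p = 0.0575 without 0 nM B). GSC, an organizer factor, fell from 57.1 ± 14.0 to 1.11 ± 0.0328 CPM (-5.68 ± 0.28, adjusted p = 0.000839), and PAX6, an eye and forebrain factor, fell with -6.28 ± 0.33. The rule's other large falls were MYL4 (-5.61 ± 0.46), NOS2 (-5.12 ± 0.23), FOXC2 (-4.83 ± 0.33), TAC4 (-4.76 ± 0.44), EDNRB (-4.56 ± 0.31) and AK5 (-4.48 ± 0.56).

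The lists of HOX genes and of anterior endoderm factors had medians of opposite sign at 100 nM. Of the 12 HOX genes of groups 1 to 5, 7 rose, among them HOXB3 (3.47 ± 0.24) and HOXB4 (3.46 ± 0.30), and 0 fell (9 and 0 adjusted over the list alone). The median log2 change was 2.71, with a camera adjusted p = 7.48e-09 and an adjusted p = 0.163 with an estimated correlation. Of the 12 MEIS, PBX, NR2F and TSHZ factors, 6 rose, among them MEIS2 (2.86 ± 0.23), TSHZ1 (2.73 ± 0.29) and MEIS1 (1.92 ± 0.16), and 1 fell, namely TSHZ3 (-1.56 ± 0.25, adjusted p 0.0513 to 0.104 without any 1 of the 4 sums compared) (7 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.000316 at a median log2 change of 0.90, and an adjusted p = 0.161 with an estimated correlation. MEIS group counts were 10 up and 2 down with the library term, and 3 up without 0 nM A, and 0 down without any 1 of the 4 sums compared. Among 17 anterior endoderm factors, 2 rose, namely NKX2-3 (2.44 ± 0.39, adjusted p = 0.0689 without 0 nM B and 0.0729 without 100 nM A) and SOX2 (1.07 ± 0.17, adjusted p 0.0511 to 0.0992 without any 1 of the 4 sums compared), and 6 fell, among them SIX3 (-3.69 ± 0.20) and HESX1 (-3.65 ± 0.27) (3 and 9 adjusted over the list alone). Their median log2 change was -0.99 (camera adjusted p = 0.00206, adjusted p = 0.163 with an estimated correlation). Anterior endoderm counts were 4 up and 11 down with the library term, and 1 up without 0 nM A or 100 nM B and 0 up without 0 nM B or 100 nM A, and 3 down without any 1 of the 4 sums compared. SIX3 and HESX1 are factors of the anterior end of the embryo, and MEIS factors are HOX cofactors. Of 4 neural crest and surface ectoderm genes, 2 rose, namely TP63 (4.05 ± 0.48) and TFAP2C (2.57 ± 0.28), and 0 fell (3 and 0 adjusted over the list alone). At a median log2 change of 1.72, the camera adjusted p was 0.000966, and an adjusted p = 0.163 with an estimated correlation. Neural crest and surface ectoderm counts were 4 up and 0 down with the library term. Neural crest and surface ectoderm camera adjusted p was 0.259 with no low-count filter, 0.127 without 0 nM B, 0.0726 without 100 nM A, 0.155 without 1 uM A, 0.3 without 1 uM B, 0.252 without 10 uM A and 0.241 without 10 uM B. The pharyngeal endoderm factors did not pass as a list (median 0.49, camera adjusted p = 0.396).

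The stress, G2 and M phase and cholesterol lists passed at 100 nM at camera's fixed correlation, but not at an estimated one. Among 14 ER and amino acid stress genes, 0 rose and 11 fell, among them TRIB3 (-3.44 ± 0.27), DDIT3 (-3.39 ± 0.14) and CHAC1 (-3.12 ± 0.21) (0 and 13 adjusted over the list alone). By camera, the list's adjusted p was 4.51e-14, and the adjusted p = 0.136 with an estimated correlation, at a median log2 change of -2.38. TRIB3, DDIT3 and CHAC1 are targets of the amino acid and endoplasmic reticulum stress factor ATF4. Of the 54 G2 and M phase genes, 23 rose, among them TOP2A (1.28 ± 0.22, adjusted p 0.0702 to 0.115 without 0 nM A, 0 nM B or 100 nM B) and MKI67 (1.28 ± 0.25, adjusted p 0.0501 to 0.143 without 0 nM A, 0 nM B, 100 nM A, 100 nM B, 10 uM A or 10 uM B), and 0 fell (38 and 1 adjusted over the list alone). Over the measured members, the median log2 change was 0.89 (camera adjusted p = 3.98e-16, adjusted p = 0.163 with an estimated correlation). G2 and M phase counts were 51 up and 1 down with the library term, and 4 up without 0 nM A or 100 nM B, 9 up without 0 nM B and 8 up without 100 nM A. Among 18 cholesterol synthesis genes, 5 rose, among them INSIG1 (1.88 ± 0.22), FDFT1 (1.21 ± 0.16, adjusted p 0.0514 to 0.0723 without 0 nM B or 100 nM A or with library totals only) and HMGCS1 (1.02 ± 0.21, adjusted p 0.0602 to 0.194 without 0 nM A, 0 nM B, 100 nM A, 100 nM B, 1 uM A or 1 uM B or with library totals only), and 0 fell (the same adjusted over the list alone). Its members had a median log2 change of 0.62, a camera adjusted p = 1.37e-05 and an adjusted p = 0.179 with an estimated correlation. Cholesterol gene counts were 17 up and 0 down with the library term, and 2 up without 0 nM B or 100 nM A and 3 up without 100 nM B, 1 uM A or 1 uM B. Median mitochondrial shares per cell were 3.10%, 4.73%, 4.54% and 5.04% in A and 3.86%, 5.96%, 5.604% and 6.18% in B at the 4 doses, lowest first, and cells of a low-depth, high-mitochondrial cluster made up 2.38%, 4.00%, 2.81% and 2.58% of A and 2.71%, 8.86%, 3.88% and 4.46% of B in the same order.

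Of the anchors, DHRS3 (1.92 ± 0.27, adjusted p = 0.0522 without 0 nM A and 0.0539 without 100 nM B) and MEIS2 (2.86 ± 0.23) rose, and SHH (-2.85 ± 0.32), a signal of the foregut floor, and OTX2 (-0.89 ± 0.14, adjusted p 0.0689 to 0.112 without any 1 of the 4 sums compared or with library totals only) fell. RARB, HOXB1, HOXA3, TBX1, EYA1, ISL1, FGF8, HHEX, FOXA2, EPCAM, GATA4 and NR2F1 did not pass (adjusted p 0.0677 to 0.854, 4.02e-16 to 0.00293 with the library term for all of these but HOXB1 and GATA4, at 0.147 and 0.399). CYP26A1 had -2.08 ± 0.53, adjusted p = 0.0614, 3.77e-21 with the library term. In edgeR's quasi-likelihood test over 17191 genes, 833 rose and 933 fell at 100 nM, 1766 in all. The library term raised this to 9101 genes, library totals without TMM gave 1031, and 1829 were called without the low-depth and mesoderm-like clusters. Leaving out 0 nM A, 0 nM B, 100 nM A or 100 nM B gave 651, 627, 569 or 613 genes. The other 24 lists had camera adjusted p-values from 0.0507 to 0.987, of which hepatic and yolk sac secretory genes (0.0556) had 0.0494, mesenchymal and EMT genes (0.0696) had 0.0489, S phase genes (0.0507) had 0.0163 and p53 response genes (0.0546) had 0.0494 with the library term. Median, mean and direction of the test differed in sign for the mesoderm genes, neural genes, WNT pathway genes, BMP pathway genes, Notch pathway genes and epithelial junction and keratin genes.

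At 1 uM against 0 nM, most factors of the posterior foregut were higher and most of the anterior and pharyngeal endoderm were lower. PDX1, a factor of the pancreas and duodenum, rose by 6.79 ± 0.42 and GATA4 from 2.81 ± 0.216 to 106 ± 8.68 CPM (5.23 ± 0.29, adjusted p = 0.000111). OTX2 fell from 262 ± 11.6 to 8.65 ± 0.255 CPM (-4.92 ± 0.16, adjusted p = 4.16e-05). By the rule for named genes (at least 20 CPM), the largest rises were those of SLC26A3, an intestinal chloride-bicarbonate exchanger (8.18 ± 0.46), ROBO2 (7.83 ± 0.26), MTTP, a microsomal triglyceride transfer protein (7.36 ± 0.19), SIM1 (7.33 ± 0.16), GABRB2 (6.65 ± 0.23), AMBP, a plasma protein precursor (6.60 ± 0.27), and FRZB, a secreted Wnt antagonist (6.57 ± 0.28). IGF2 was also among them (6.62 ± 0.29), but its locus overlaps readthrough genes, so its count is uncertain. The rule's largest falls were EDNRB (-7.73 ± 0.42), AK5 (-7.17 ± 0.73), DMBX1 (-7.06 ± 0.20) and FGF5 (-7.06 ± 0.34) and TAC4 (-6.88 ± 0.55), CNTN6 (-6.80 ± 0.33), NOS2 (-6.60 ± 0.26) and SHISA2 (-6.55 ± 0.38).

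HOX genes of groups 1 to 5 rose at 1 uM, as did most of the MEIS, PBX, NR2F and TSHZ factors. Of 12 HOX genes of groups 1 to 5, 12 rose, among them HOXA3 (6.12 ± 0.34) and HOXC5 (5.97 ± 0.21), and 0 fell (the same adjusted over the list alone). Camera's test of the list gave an adjusted p = 3.3e-11, and an adjusted p = 0.163 with an estimated correlation, at a median log2 change of 5.76. Of the 3 HOX genes of groups 6 to 13, 2 rose, namely HOXB7 (44.8-fold higher, 7.49 to 1825, adjusted p 0.0521 to 0.0825 without any 1 of the 4 sums compared) and HOXB13 (16.1-fold higher, 3.98 to 141, adjusted p 0.0524 to 0.0705 without 0 nM A, 0 nM B or 1 uM A), and 0 fell (3 and 0 adjusted over the list alone). This group had a median log2 change of 3.77, with a camera adjusted p = 0.0205 and an adjusted p = 0.180 with an estimated correlation, and 0.106 with the library term. Posterior HOX counts were 0 up without 0 nM A, 0 nM B or 1 uM A and 1 up without 1 uM B. Posterior HOX camera adjusted p was 0.218 with no low-count filter. Among 12 MEIS, PBX, NR2F and TSHZ factors, 9 rose, among them NR2F1 (4.45 ± 0.52) and TSHZ1 (3.71 ± 0.29), and 1 fell, namely PBX3 (-1.37 ± 0.30, adjusted p 0.0886 to 0.102 without 0 nM A or 1 uM B or with library totals only) (the same adjusted over the list alone). For the list, the median log2 change was 2.00 (camera adjusted p = 0.000355, adjusted p = 0.161 with an estimated correlation). MEIS group counts were 10 up and 2 down with the library term, and 0 down without 0 nM A or 1 uM B.

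Lists of regional endoderm factors had medians of opposite sign. Of 13 posterior foregut factors, 13 rose, among them ONECUT1 (6.37 ± 0.25) and MNX1 (6.00 ± 0.20), and 0 fell (the same adjusted over the list alone). As a list, its median log2 change was 4.27, with a camera adjusted p = 1.74e-11 and an adjusted p = 0.0875 with an estimated correlation. Of the 14 hepatic and yolk sac secretory genes, 8 rose, among them SERPINA1 (6.05 ± 0.39), and 1 fell, namely RBP4 (-5.49 ± 0.41) (10 and 1 adjusted over the list alone). The median log2 change was 5.35, or 2.81 with genes at 0 counts set to their bound, with a camera adjusted p = 0.000382 and an adjusted p = 0.179 with an estimated correlation. Hepatic and yolk sac counts were 5 up without 0 nM A, 0 nM B or 1 uM B. Of 4 mid and hindgut factors, 2 rose, namely CDX2 (6.53 ± 0.58) and VIL1 (2.67 ± 0.22), and 0 fell (3 and 0 adjusted over the list alone). Camera gave an adjusted p = 0.0138 at a median log2 change of 3.28, and an adjusted p = 0.179 with an estimated correlation, and 0.0851 with the library term. Mid and hindgut counts were 4 up and 0 down with the library term. Mid and hindgut camera adjusted p was 0.124 with no low-count filter. Among 17 anterior endoderm factors, 4 rose, namely FRZB (6.57 ± 0.28), FOXA1 (2.71 ± 0.28), FOXA3 (1.70 ± 0.26) and SOX2 (0.60 ± 0.17, adjusted p 0.0643 to 0.207 without any 1 of the 8 sums or with no low-count filter), and 9 fell, among them FOXE1 (-6.48 ± 0.43), SIX3 (-6.07 ± 0.23) and DKK1 (-5.33 ± 0.65) (4 and 10 adjusted over the list alone). Their median log2 change was -3.10 (camera adjusted p = 0.0126, adjusted p = 0.180 with an estimated correlation, and 0.232 with the library term). Anterior endoderm camera adjusted p was 0.0809 with the 10 CPM filter. Of 19 pharyngeal endoderm factors, 1 rose, namely EYA4 (35.0-fold higher, 5.73 to 1438, adjusted p 0.0558 to 0.106 without any 1 of the 4 sums compared), and 15 fell, among them GATA3 (-5.12 ± 0.38), FGF8 (-4.98 ± 0.54) and EYA1 (-3.67 ± 0.28) (1 and 16 adjusted over the list alone). At a median log2 change of -3.16, or -2.88 with genes at 0 counts set to their bound, the camera adjusted p was 7.2e-10, and an adjusted p = 0.161 with an estimated correlation. Pharyngeal counts were 0 up without any 1 of the 4 sums compared. Of the pouch factors, PAX1 was 19.3-fold lower, 5.08 to 163, and PAX9, with 3 counts at 1 uM, did not pass with dose alone (adjusted p = 0.0609, 0.00255 with the library term).

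Signalling lists of 4 pathways passed at camera's fixed correlation, but not at an estimated one. Among 22 FGF pathway genes, 4 rose, namely FGF19 (at least 9.34-fold higher, adjusted p 0.0713 to 0.107 without any 1 of the 4 sums compared), DUSP4 (3.81 ± 0.13), FGFR4 (3.76 ± 0.17) and FGFR2 (0.57 ± 0.12, adjusted p 0.0524 to 0.130 without any 1 of the 4 sums compared or with library totals only or with no low-count filter), and 12 fell, among them FGF8 (-4.98 ± 0.54) (4 and 13 adjusted over the list alone). By camera, the list's adjusted p was 0.00683, and the adjusted p = 0.163 with an estimated correlation, at a median log2 change of -1.38. FGF pathway counts were 2 up without any 1 of the 4 sums compared. FGF pathway camera adjusted p was 0.0969 with the 10 CPM filter. Of 19 BMP pathway genes, 3 rose, namely BMP5 (18.2-fold higher, 4.56 to 158, adjusted p = 0.0598 without 0 nM A and 0.0571 without 0 nM B), BMP7 (1.53 ± 0.12) and CHRD (1.48 ± 0.25, adjusted p = 0.0530 without 0 nM A), and 10 fell, among them FST (-5.68 ± 0.16), BAMBI (-5.63 ± 0.33) and BMP4 (-5.32 ± 0.20) (4 and 11 adjusted over the list alone). Over the measured members, the median log2 change was -1.34 (camera adjusted p = 0.00659, adjusted p = 0.284 with an estimated correlation). BMP pathway counts were 6 up and 12 down with the library term, and 1 up without 0 nM A. Of the 11 Hedgehog pathway genes, 1 rose, namely IHH (123-fold higher, 33.4 to 1020.0), and 7 fell, among them GLI1 (-4.92 ± 0.51), HHIP (-4.28 ± 0.29) and SHH (-3.37 ± 0.33) (2 and 8 adjusted over the list alone). Its members had a median log2 change of -2.05, a camera adjusted p = 0.00510 and an adjusted p = 0.163 with an estimated correlation. Hedgehog pathway counts were 2 up and 8 down with the library term. Among 14 Notch pathway genes, 6 rose, among them HEY2 (3.68 ± 0.42) and HES1 (2.14 ± 0.23), and 1 fell, namely LFNG (47.8-fold lower, 13 to 399) (the same adjusted over the list alone). Camera's test of the list gave an adjusted p = 0.0142, and an adjusted p = 0.179 with an estimated correlation, at a median log2 change of 0.62. Notch pathway counts were 9 up and 2 down with the library term.

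The S phase, stress, cholesterol and epithelial lists passed at 1 uM at camera's fixed correlation, but not at an estimated one. Of the 43 S phase genes, 0 rose and 23 fell, among them CDC6 (-1.64 ± 0.13) and MCM6 (-1.58 ± 0.13) (0 and 32 adjusted over the list alone). This group had a median log2 change of -0.91, with a camera adjusted p = 8.38e-11 and an adjusted p = 0.168 with an estimated correlation. S phase counts were 0 up and 43 down with the library term, and 14 down without 0 nM A, 15 down without 1 uM A and 13 down without 1 uM B. Of 14 ER and amino acid stress genes, 0 rose and 13 fell, among them CHAC1 (-5.46 ± 0.25) and PSAT1 (-4.80 ± 0.32) (the same adjusted over the list alone). For the list, the median log2 change was -3.22 (camera adjusted p = 1.01e-10, adjusted p = 0.157 with an estimated correlation). Of the 18 cholesterol synthesis genes, 5 rose, among them INSIG1 (2.52 ± 0.22), FDFT1 (1.18 ± 0.16) and HMGCS1 (1.01 ± 0.21, adjusted p 0.0957 to 0.106 without 0 nM B or 1 uM A or with library totals only), and 0 fell (6 and 0 adjusted over the list alone). As a list, its median log2 change was 0.78, with a camera adjusted p = 0.000899 and an adjusted p = 0.22 with an estimated correlation. Cholesterol gene counts were 17 up and 0 down with the library term, and 3 up without 0 nM B or 1 uM A. Of 19 epithelial junction and keratin genes, 6 rose, among them CDH6 (5.27 ± 0.33) and LAMA1 (2.00 ± 0.15), and 0 fell (7 and 0 adjusted over the list alone). The median log2 change was 0.51, with a camera adjusted p = 0.00891 and an adjusted p = 0.199 with an estimated correlation. Epithelial gene counts were 15 up and 3 down with the library term. Median mitochondrial shares per cell were 4.54% in A and 5.604% in B at 1 uM.

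Of the anchors, DHRS3 (4.28 ± 0.30), NR2F1 (4.45 ± 0.52), MEIS2 (3.05 ± 0.24), HOXB3 (5.13 ± 0.24) and SOX2 (0.60 ± 0.17, adjusted p 0.0643 to 0.207 without any 1 of the 8 sums or with no low-count filter) rose, and ISL1 (-3.16 ± 0.18) and TBX1 (-1.31 ± 0.32, adjusted p 0.0556 to 0.141 without 0 nM B, 1 uM A or 1 uM B) fell. HOXB1 was 20.6-fold higher, 6.59 to 104 (adjusted p 0.0541 to 0.180 without 0 nM A, 0 nM B, 1 uM A, 10 uM A or 10 uM B or with library totals only or with equal cells per sum). CYP26A1, RARB, HHEX, FOXA2 and EPCAM did not pass (adjusted p 0.177 to 0.800, 8.43e-22 to 3.82e-06 with the library term). By edgeR, 2397 genes rose and 2053 fell, 4450 in all. The library term gave 11264, and a filter of 10 CPM in 2 sums, which tests fewer genes, gave 2957. Leaving out 0 nM A, 0 nM B, 1 uM A or 1 uM B gave 2657, 2751, 2627 or 2672 genes. The other 15 lists did not pass. Their median log2 changes and camera adjusted p-values were those of RA response genes (1.15, 0.0507, 0.0256 with the library term), RA synthesis and receptors (0.31, 0.103), definitive endoderm genes (0.71, 0.928), pluripotency genes (-0.45, 0.212) and mesoderm genes (0.45, 0.482). Next came endothelial and blood genes (0.34, 0.738), neural genes (-0.77, 0.175), neural crest and surface ectoderm genes (0.17, 0.858), WNT pathway genes (0.16, 0.946) and NODAL and TGF-beta pathway genes (0.09, 0.980), followed by mesenchymal and EMT genes (0.38, 0.0878), G2 and M phase genes (0.10, 0.843), p53 response genes (-0.28, 0.344), immediate early and heat shock genes (-0.00259, 0.997) and hypoxia and glycolysis genes (-0.46, 0.118, 0.0487 with the library term). Median, mean and direction of the test differed in sign for the definitive endoderm genes (mean -0.10, test up), WNT pathway genes (mean -0.13, test up), NODAL and TGF-beta pathway genes (mean -0.10, test up) and immediate early and heat shock genes (mean -0.06, test up).

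**Figure D2:**
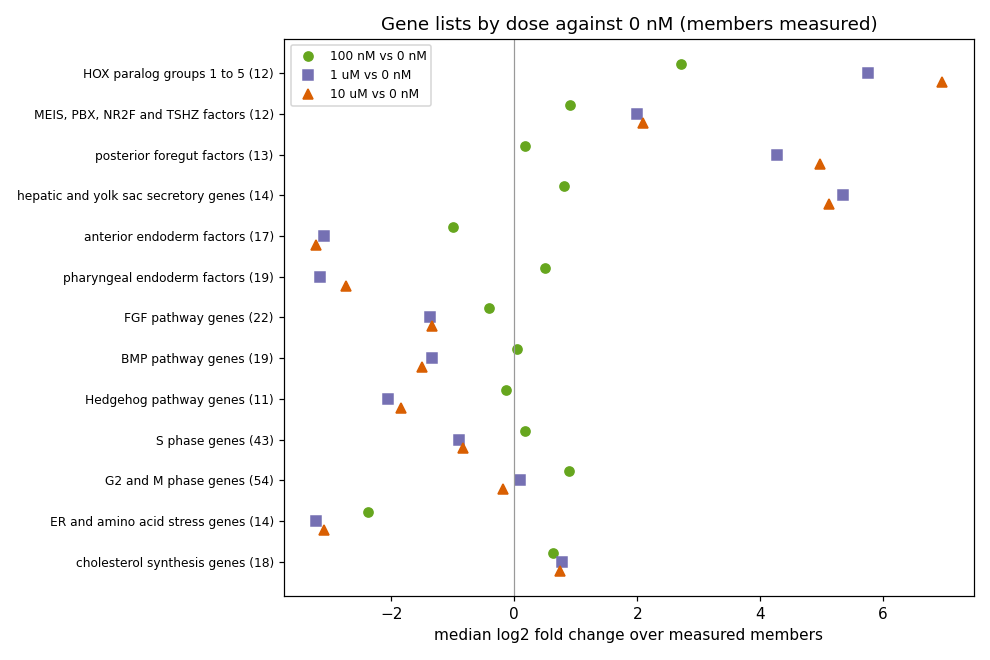
Median log2 change over the measured members of 13 gene lists (vertical axis) for 100 nM, 1 uM and 10 uM against 0 nM, with circles, squares and triangles for the 3 doses. The HOX genes of groups 1 to 5 have medians of 2.71, 5.76 and 6.96, and the pharyngeal endoderm factors 0.49, -3.16 and -2.74.

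At 10 uM against 0 nM, the posterior foregut and pharyngeal lists had the directions they had at 1 uM. CYP26B1, a retinoic acid-degrading enzyme, rose by 6.65 ± 0.30 and DHRS3 from 8.10 ± 2.33 to 233 ± 44.5 CPM (4.84 ± 0.30, adjusted p = 0.000148). By the rule for named genes (at least 20 CPM), the largest rises were those of SLC26A3 (8.04 ± 0.46), FGB, a fibrinogen chain (7.89 ± 0.78), HOXA4 (7.64 ± 0.30), HOXA5 (7.53 ± 0.24), HOXB4 (7.45 ± 0.31), ROBO2 (7.32 ± 0.26), DIO1, the type 1 deiodinase (7.30 ± 0.59), and VIPR2, a receptor for vasoactive intestinal peptide (7.28 ± 0.56). The rule's largest falls were AK5 (-7.70 ± 0.76), FGF5 (-7.51 ± 0.35), EDNRB (-7.43 ± 0.40) and SULF1 (-7.31 ± 0.35) and PAX6 (-7.27 ± 0.37), DKK1 (-7.15 ± 0.75), TAC4 (-6.95 ± 0.55) and DMBX1 (-6.94 ± 0.19).

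The retinoic acid response list passed against 0 nM at this dose at camera's fixed correlation, but not at an estimated one. Among 15 RA response genes, 9 rose, among them CYP26B1 (6.65 ± 0.30) and PLAAT4 (5.04 ± 0.27), and 3 fell, namely CYP26C1 (-5.91 ± 0.49), CRABP2 (-2.68 ± 0.15) and STRA6 (-0.95 ± 0.21, adjusted p 0.0677 to 0.110 without 0 nM A or 10 uM A or with library totals only) (10 and 3 adjusted over the list alone). Camera gave an adjusted p = 0.00450 at a median log2 change of 2.32, and an adjusted p = 0.163 with an estimated correlation. Among 12 HOX genes of groups 1 to 5, 12 rose, among them HOXB5 (7.22 ± 0.66) and HOXA3 (7.14 ± 0.35), and 0 fell (the same adjusted over the list alone). Their median log2 change was 6.96 (camera adjusted p = 4.26e-12, adjusted p = 0.161 with an estimated correlation). Among 3 HOX genes of groups 6 to 13, 2 rose, namely HOXB13 (94.3-fold higher, 25.6 to 786) and HOXB7 (54.1-fold higher, 9.18 to 2187, adjusted p = 0.0613 without 0 nM B), and 0 fell (3 and 0 adjusted over the list alone). At a median log2 change of 5.41, the camera adjusted p was 0.0131, and an adjusted p = 0.179 with an estimated correlation, and 0.0849 with the library term. Posterior HOX counts were 1 up without 0 nM B. Of 12 MEIS, PBX, NR2F and TSHZ factors, 7 rose, among them TSHZ1 (4.62 ± 0.29) and NR2F1 (3.98 ± 0.51), and 1 fell, namely PBX3 (-1.65 ± 0.30, adjusted p = 0.0509 with library totals only and 0.0591 without 10 uM B) (7 and 2 adjusted over the list alone). By camera, the list's adjusted p was 0.00601, and the adjusted p = 0.163 with an estimated correlation, at a median log2 change of 2.09. MEIS group counts were 9 up and 2 down with the library term, and 0 down without 10 uM B.

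Among the regional endoderm factors, most of those of the posterior foregut and liver rose. Of the 13 posterior foregut factors, 13 rose, among them PDX1 (6.71 ± 0.42) and MNX1 (6.53 ± 0.20), and 0 fell (the same adjusted over the list alone). Over the measured members, the median log2 change was 4.98 (camera adjusted p = 2.26e-11, adjusted p = 0.0875 with an estimated correlation). Among 14 hepatic and yolk sac secretory genes, 9 rose, among them FGB (7.89 ± 0.78), and 1 fell, namely RBP4 (-5.68 ± 0.42) (10 and 1 adjusted over the list alone). Its members had a median log2 change of 5.12, or 3.38 with genes at 0 counts set to their bound, a camera adjusted p = 0.000321 and an adjusted p = 0.179 with an estimated correlation. Hepatic and yolk sac counts were 5 up without 0 nM B. Of the 4 mid and hindgut factors, 2 rose, namely CDX2 (6.86 ± 0.58) and VIL1 (3.36 ± 0.22), and 0 fell (the same adjusted over the list alone). Camera's test of the list gave an adjusted p = 0.0147, and an adjusted p = 0.179 with an estimated correlation, and 0.0851 with the library term, at a median log2 change of 3.67. Mid and hindgut counts were 4 up and 0 down with the library term. Of 17 anterior endoderm factors, 3 rose, namely FRZB (5.63 ± 0.27), FOXA1 (2.40 ± 0.27) and FOXA3 (1.64 ± 0.26), and 10 fell, among them DKK1 (-7.15 ± 0.75) and FOXE1 (-6.17 ± 0.41) (the same adjusted over the list alone). This group had a median log2 change of -3.23, with a camera adjusted p = 0.00965 and an adjusted p = 0.179 with an estimated correlation, and 0.172 with the library term. Anterior endoderm counts were 6 up and 11 down with the library term. Of the 19 pharyngeal endoderm factors, 1 rose, namely EYA4 (26.4-fold higher, 4.22 to 1093, adjusted p 0.0548 to 0.159 without 0 nM A, 0 nM B, 1 uM A, 1 uM B or 10 uM A), and 15 fell, among them FGF8 (-6.22 ± 0.60) and GATA3 (-5.73 ± 0.40) (the same adjusted over the list alone). For the list, the median log2 change was -2.74 (camera adjusted p = 9.75e-10, adjusted p = 0.161 with an estimated correlation). Pharyngeal counts were 0 up without 0 nM A, 0 nM B, 1 uM A, 1 uM B or 10 uM A.

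The FGF, BMP and Hedgehog lists passed here too, downward, at camera's fixed correlation, but not at an estimated one. Of 22 FGF pathway genes, 2 rose, namely DUSP4 (3.89 ± 0.13) and FGFR4 (3.83 ± 0.17), and 11 fell, among them FGF8 (-6.22 ± 0.60) and ETV5 (-5.19 ± 0.55) (4 and 13 adjusted over the list alone). As a list, its median log2 change was -1.34, with a camera adjusted p = 0.00609 and an adjusted p = 0.163 with an estimated correlation. FGF pathway counts were 4 up and 14 down with the library term. FGF pathway camera adjusted p was 0.103 with the 10 CPM filter. Of the 19 BMP pathway genes, 2 rose, namely BMP7 (1.47 ± 0.12) and CHRD (1.06 ± 0.25, adjusted p 0.0743 to 0.120 without any 1 of the 4 sums compared), and 9 fell, among them BAMBI (-5.47 ± 0.33) and BMP4 (-5.44 ± 0.20) (3 and 9 adjusted over the list alone). The median log2 change was -1.51, with a camera adjusted p = 0.0120 and an adjusted p = 0.314 with an estimated correlation. BMP pathway counts were 6 up and 12 down with the library term, and 1 up without 0 nM A, 0 nM B or 10 uM A. Of 11 Hedgehog pathway genes, 1 rose, namely IHH (107-fold higher, 29.1 to 889.5), and 8 fell, among them HHIP (-5.49 ± 0.32) and GLI1 (-4.78 ± 0.50) (the same adjusted over the list alone). Camera gave an adjusted p = 0.00263 at a median log2 change of -1.84, and an adjusted p = 0.163 with an estimated correlation. Hedgehog pathway counts were 2 up and 8 down with the library term. Among 43 S phase genes, 0 rose and 21 fell, among them MCM6 (-1.51 ± 0.13) and CDC6 (-1.44 ± 0.13) (0 and 25 adjusted over the list alone). Their median log2 change was -0.83 (camera adjusted p = 2.16e-09, adjusted p = 0.179 with an estimated correlation). S phase counts were 0 up and 42 down with the library term, and 12 down without 0 nM A, 10 uM A or 10 uM B. Of the 14 ER and amino acid stress genes, 0 rose and 13 fell, among them CHAC1 (-5.61 ± 0.25) and PSAT1 (-4.84 ± 0.32) (the same adjusted over the list alone). At a median log2 change of -3.09, the camera adjusted p was 3.84e-10, and an adjusted p = 0.157 with an estimated correlation. Of 18 cholesterol synthesis genes, 6 rose, among them INSIG1 (2.40 ± 0.22) and FDFT1 (1.28 ± 0.16), and 0 fell (7 and 0 adjusted over the list alone). By camera, the list's adjusted p was 0.000579, and the adjusted p = 0.210 with an estimated correlation, at a median log2 change of 0.74. Cholesterol gene counts were 17 up and 0 down with the library term, and 3 up without 10 uM A. Of the 19 epithelial junction and keratin genes, 6 rose, among them CDH6 (4.48 ± 0.32) and LAMA1 (2.05 ± 0.15), and 1 fell, namely ESRP1 (-0.43 ± 0.11, adjusted p 0.0638 to 0.293 without any 1 of the 8 sums or with library totals only or with no low-count filter) (6 and 3 adjusted over the list alone). Over the measured members, the median log2 change was 0.53 (camera adjusted p = 0.0311, adjusted p = 0.253 with an estimated correlation). Epithelial gene counts were 13 up and 5 down with the library term, and 0 down without any 1 of the 8 sums. Epithelial gene camera adjusted p was 0.0574 without 0 nM B. Median mitochondrial shares per cell were 5.04% in A and 6.18% in B at 10 uM.

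CYP26A1, the classical feedback enzyme, rose against 0 nM (2.32 ± 0.53; adjusted p 0.0553 to 0.104 without 0 nM B or 10 uM A or with library totals only). GATA4 (5.40 ± 0.29), MEIS2 (3.22 ± 0.24) and HOXB3 (6.52 ± 0.25) rose, HOXB1 was 113-fold higher, 38.2 to 551, and ISL1 (-3.72 ± 0.19), SHH (-3.94 ± 0.34) and TBX1 (-1.83 ± 0.32, adjusted p = 0.0560 without 10 uM A) fell. RARB, PAX9, SOX2, HHEX, FOXA2 and EPCAM did not pass (adjusted p 0.124 to 0.770, 1.29e-22 to 0.0170 with the library term). By edgeR, 2578 genes rose and 2237 fell, 4815 in all, against 11609 with the library term and 3137 with the filter of 10 CPM in 2 sums. Without 0 nM A, 0 nM B, 10 uM A or 10 uM B, the count was 3136, 3158, 3005 or 3166. The other 15 lists had camera adjusted p-values from 0.0556 to 0.980, of which G2 and M phase genes (0.0881) had 0.0494 with the library term.

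Between 100 nM and 1 uM, most pharyngeal endoderm factors fell and most posterior foregut factors rose. At 1 uM, PAX9 was 196-fold lower, 66.9 to 952 (866 counts against 3), and PAX1 was 269-fold lower, 74.3 to 2227 (793 counts against 2). EYA1 fell from 49.2 ± 7.63 to 2.30 ± 0.828 CPM (-4.39 ± 0.29, adjusted p = 0.000307). PDX1 (6.62 ± 0.41) and GATA4 (5.43 ± 0.29) rose. By the rule for named genes (at least 20 CPM, which PDX1 and PAX1 did not reach), the largest rises were those of SIM1 (7.25 ± 0.16), FRZB (6.75 ± 0.29), BMP3, an inhibitory BMP ligand (6.71 ± 0.49), SLC26A3 (6.54 ± 0.40) and the carboxypeptidase M gene (6.09 ± 0.29). The rule's largest falls besides PAX9 were SULF1 (-5.99 ± 0.33), FABP7 (-5.84 ± 0.31), OTX1 (-5.63 ± 0.31) and GALNT14 (-5.43 ± 0.43).

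More HOX genes and retinoic acid response genes rose than fell between these doses. Of the 15 RA response genes, 7 rose, among them LRAT (4.52 ± 0.18) and PLAAT4 (3.79 ± 0.24), and 3 fell, namely CYP26C1 (-3.19 ± 0.44), CRABP2 (-2.36 ± 0.14) and STRA6 (-1.21 ± 0.20, adjusted p = 0.0537 without 100 nM A and 0.0696 without 1 uM B) (the same adjusted over the list alone). Its members had a median log2 change of 0.66, a camera adjusted p = 0.0480 and an adjusted p = 0.199 with an estimated correlation. RA response camera adjusted p was 0.0508 without called doublets, 0.0866 with equal cells per sum, 0.0501 without cycle, mitochondrial and ribosomal genes, 0.0550 without the cells of highest doublet score and 0.0510 without 100 nM B. Of 12 HOX genes of groups 1 to 5, 10 rose, among them HOXA5 (5.74 ± 0.23) and HOXA4 (5.01 ± 0.28), and 0 fell (11 and 0 adjusted over the list alone). Camera's test of the list gave an adjusted p = 7.06e-09, and an adjusted p = 0.163 with an estimated correlation, at a median log2 change of 2.50. Of 3 HOX genes of groups 6 to 13, 3 rose, namely HOXA7 (at least 7.85-fold higher, adjusted p 0.0718 to 0.135 without 100 nM A, 100 nM B, 1 uM A, 1 uM B, 10 uM A or 10 uM B), HOXB7 (47.1-fold higher, 7.87 to 1919, adjusted p 0.0561 to 0.111 without any 1 of the 4 sums compared or with equal cells per sum) and HOXB13 (16.9-fold higher, 4.18 to 148, adjusted p = 0.0643 without 1 uM A and 0.0604 without 1 uM B), and 0 fell (the same adjusted over the list alone). This group had a median log2 change of 5.17, or 3.86 with genes at 0 counts set to their bound, with a camera adjusted p = 0.00804 and an adjusted p = 0.175 with an estimated correlation, and 0.0757 with the library term. Posterior HOX counts were 1 up without 100 nM A or 100 nM B and 0 up without 1 uM A or 1 uM B. Of the 12 MEIS, PBX, NR2F and TSHZ factors, 7 rose, among them NR2F1 (3.86 ± 0.51) and TSHZ3 (2.76 ± 0.26), and 2 fell, namely PBX3 (-2.29 ± 0.30) and NR2F2 (-0.99 ± 0.18, adjusted p 0.0582 to 0.0945 without 100 nM B, 1 uM A or 1 uM B) (the same adjusted over the list alone). For the list, the median log2 change was 0.93 (camera adjusted p = 0.0347, adjusted p = 0.188 with an estimated correlation). MEIS group counts were 3 up without 100 nM A or 100 nM B and 4 up without 1 uM A or 1 uM B, and 1 down without 100 nM B, 1 uM A or 1 uM B. MEIS group camera adjusted p was 0.0542 with equal cells per sum.

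Regional and signalling lists passed between these doses at camera's fixed correlation, but not at an estimated one. Among 19 pharyngeal endoderm factors, 1 rose, namely EYA4 (18.4-fold higher, 4.59 to 160.3, adjusted p 0.05 to 0.162 without 100 nM A, 100 nM B, 1 uM A, 1 uM B or 10 uM A or with library totals only), and 17 fell, among them GATA3 (-4.56 ± 0.37) and EYA1 (-4.39 ± 0.29) (the same adjusted over the list alone). As a list, its median log2 change was -3.15, with a camera adjusted p = 1.36e-12 and an adjusted p = 0.157 with an estimated correlation. Pharyngeal counts were 0 up without 100 nM A, 100 nM B, 1 uM A, 1 uM B or 10 uM A. Among 13 posterior foregut factors, 11 rose, among them PDX1 (6.62 ± 0.41) and HNF4A (5.14 ± 0.29), and 0 fell (12 and 0 adjusted over the list alone). The median log2 change was 3.99, with a camera adjusted p = 3.13e-12 and an adjusted p = 0.0875 with an estimated correlation. Of 14 hepatic and yolk sac secretory genes, 5 rose, namely SERPINA1 (104-fold higher, 35.0 to 506), APOA1 (4.54 ± 0.18), FGB (4.02 ± 0.64), FGA (3.47 ± 0.33) and VTN (1.27 ± 0.22, adjusted p 0.0518 to 0.0746 without 100 nM B or 1 uM A or with library totals only), and 0 fell (6 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.00159 at a median log2 change of 1.93, and an adjusted p = 0.199 with an estimated correlation. Hepatic and yolk sac counts were 9 up and 1 down with the library term, and 1 down without 10 uM A or 10 uM B. Among 19 BMP pathway genes, 2 rose, namely CHRD (1.94 ± 0.26) and BMP7 (1.04 ± 0.12), and 10 fell, among them GREM1 (-4.73 ± 0.30) and BMP4 (-4.26 ± 0.19) (3 and 11 adjusted over the list alone). Their median log2 change was -1.19 (camera adjusted p = 0.000207, adjusted p = 0.199 with an estimated correlation). Among 11 Hedgehog pathway genes, 1 rose, namely IHH (2.68 ± 0.39), and 6 fell, among them GLI1 (-3.90 ± 0.53) and GLI2 (-3.82 ± 0.32) (1 and 7 adjusted over the list alone). At a median log2 change of -0.73, the camera adjusted p was 0.00601, and an adjusted p = 0.163 with an estimated correlation. Hedgehog pathway counts were 3 down without 100 nM A, 1 uM A or 1 uM B. Among 19 epithelial junction and keratin genes, 8 rose, among them CDH1 (1.41 ± 0.15), and 2 fell, namely KRT7 (-1.77 ± 0.35, adjusted p 0.0679 to 0.0878 without 100 nM A or 1 uM B or with library totals only) and GRHL2 (-0.92 ± 0.13) (11 and 2 adjusted over the list alone). By camera, the list's adjusted p was 0.00510, and the adjusted p = 0.183 with an estimated correlation, at a median log2 change of 0.82. Epithelial gene counts were 14 up and 3 down with the library term, and 3 up without 100 nM A or 1 uM B and 1 up without 100 nM B or 1 uM A, and 1 down without 100 nM A or 1 uM B.

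The cycle and stress lists had medians below 0. Of 43 S phase genes, 0 rose and 32 fell, among them EXO1 (-1.69 ± 0.20) and CDCA7 (-1.69 ± 0.14) (0 and 37 adjusted over the list alone). Over the measured members, the median log2 change was -1.16 (camera adjusted p = 3.98e-16, adjusted p = 0.163 with an estimated correlation). S phase counts were 20 down without 100 nM A or 1 uM A and 18 down without 1 uM B. Among 54 G2 and M phase genes, 0 rose and 29 fell, among them PIMREG (-1.88 ± 0.14) and HJURP (-1.09 ± 0.14) (0 and 36 adjusted over the list alone). Its members had a median log2 change of -0.85, a camera adjusted p = 9.19e-13 and an adjusted p = 0.163 with an estimated correlation. G2 and M phase counts were 0 up and 53 down with the library term, and 11 down without 100 nM A, 7 down without 100 nM B, 5 down without 1 uM A and 9 down without 1 uM B. Of 14 ER and amino acid stress genes, 1 rose, namely ATF3 (0.77 ± 0.12, adjusted p = 0.0682 with library totals only and 0.0554 without 100 nM B), and 9 fell, among them PSAT1 (-2.38 ± 0.29) and CHAC1 (-2.33 ± 0.23) (the same adjusted over the list alone). Camera's test of the list gave an adjusted p = 0.00659, and an adjusted p = 0.208 with an estimated correlation, at a median log2 change of -0.78. Stress gene counts were 3 up and 10 down with the library term, and 0 up without 100 nM B, and 3 down without 100 nM A or 1 uM B, 4 down without 100 nM B, 2 down without 1 uM A and 5 down without 10 uM A or 10 uM B.

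Of the anchors, DHRS3 (2.36 ± 0.27), CYP26A1 (2.63 ± 0.54, adjusted p 0.0543 to 0.114 without 100 nM A, 100 nM B or 1 uM A or with library totals only), NR2F1 (3.86 ± 0.51), HOXB3 (1.66 ± 0.19) and HHEX (1.68 ± 0.33, adjusted p 0.0699 to 0.0987 without 100 nM B or 1 uM A or with library totals only) rose, and OTX2 (-4.02 ± 0.16), TBX1 (-1.88 ± 0.32, adjusted p = 0.0686 without 1 uM A) and FGF8 (-3.42 ± 0.54, adjusted p = 0.0517 without 1 uM B) fell. RARB, HOXB1, SOX2, FOXA2, EPCAM, MEIS2 and SHH did not pass (adjusted p 0.105 to 0.996, 3.02e-21 to 0.00617 with the library term for all of these but RARB, at 0.964). By edgeR, 1845 genes rose and 1419 fell, 3264 in all, against 10159 with the library term. Without 100 nM A, 100 nM B, 1 uM A or 1 uM B, the count was 1675, 1746, 1687 or 1760.0. The other 18 lists had camera adjusted p-values from 0.0560 to 0.843. Median, mean and direction of the test differed in sign for the NODAL and TGF-beta pathway genes, p53 response genes and hypoxia and glycolysis genes.

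Between 1 uM and 10 uM, no single gene passed the test without the library term, and the HOX genes of groups 1 to 5 had the lowest p of the list tests by camera at its fixed correlation (adjusted p = 0.161 with an estimated correlation, so the call was lost). HOXA5 stood at 27.2 ± 0.808 CPM at 1 uM and 95.6 ± 2.17 CPM at 10 uM (1.81 ± 0.17, adjusted p = 0.0694, 1.6e-24 with the library term). HOXB4 had 1.61 ± 0.21 (adjusted p = 0.0906, 1.08e-20 with the library term), and HOXA3 had 1.02 ± 0.25 (adjusted p = 0.3, 6.38e-18 with the library term). CYP26A1 stood at 277 ± 121 and 939.9 ± 429 CPM (1.76 ± 0.52, adjusted p = 0.428, 7.62e-21 with the library term). edgeR called 0 genes in either direction over 17191 tested, with 1146 genes at an unadjusted p under 0.05. DESeq2 called 197 (148 up and 49 down), edgeR without the low-count filter 26, and edgeR on equal cells per sum 6. With the library term, edgeR called 2878 genes, 1589 up and 1289 down, and 398 of at least 2-fold. Leaving out 1 uM A or 10 uM A took the count with the library term to 1798 or 1813.

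Among the lists, of the 12 HOX genes of groups 1 to 5, 0 rose and 0 fell (9 and 0 adjusted over the list alone, among them HOXA4 at 1.85 ± 0.20 and adjusted p = 0.000453, HOXA5 at 1.81 ± 0.17 and adjusted p = 0.000415 and HOXB4 at 1.61 ± 0.21 and adjusted p = 0.000736). This group had a median log2 change of 1.49, with a camera adjusted p = 2.93e-13 and an adjusted p = 0.161 with an estimated correlation. HOX counts were 10 up and 0 down with the library term. Of 15 RA response genes, 0 rose and 0 fell (2 and 0 adjusted over the list alone, namely CYP26B1 at 1.66 ± 0.22 and adjusted p = 0.00187 and HIC1 at 2.46 ± 0.33 and adjusted p = 0.00187). For the list, the median log2 change was 0.34 (camera adjusted p = 0.00891, adjusted p = 0.168 with an estimated correlation). RA response counts were 9 up and 2 down with the library term. RA response camera adjusted p was 0.102 without 10 uM B. Of the 9 neural genes, 0 rose and 0 fell (1 and 2 adjusted over the list alone, namely SOX3 at 0.98 ± 0.26 and adjusted p = 0.0400, DCX at -1.82 ± 0.42 and adjusted p = 0.0400 and ZIC1 at -0.82 ± 0.25 and adjusted p = 0.0444). As a list, its median log2 change was -0.72, with a camera adjusted p = 0.0149 and an adjusted p = 0.179 with an estimated correlation, and 0.0802 with the library term. Neural gene counts were 0 up and 3 down with the library term. Neural gene camera adjusted p was 0.0712 with no low-count filter, 0.866 with the 10 CPM filter, 0.0719 with equal cells per sum, 0.209 without the cells of highest doublet score and 0.152 without 1 uM A. Among 11 NODAL and TGF-beta pathway genes, 0 rose and 0 fell (2 and 0 adjusted over the list alone, namely INHBB at 3.21 ± 0.54 and adjusted p = 0.0175 and TGFBI at 1.66 ± 0.43 and adjusted p = 0.0411). The median log2 change was 0.24, with a camera adjusted p = 0.00570 and an adjusted p = 0.163 with an estimated correlation, and 0.0583 with the library term. NODAL pathway counts were 4 up and 1 down with the library term. NODAL pathway camera adjusted p was 0.0555 with no low-count filter, 0.725 with the 10 CPM filter, 0.103 without 1 uM B and 0.0578 without 10 uM A.

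GDF15, a stress-induced ligand, belonged to a further list. Of 16 p53 response genes, 0 rose and 0 fell (2 and 0 adjusted over the list alone, namely GDF15 at 1.69 ± 0.18 and adjusted p = 0.00113 and ZMAT3 at 0.66 ± 0.15 and adjusted p = 0.0347). Camera gave an adjusted p = 0.00385 at a median log2 change of 0.28, and an adjusted p = 0.179 with an estimated correlation. P53 response counts were 8 up and 0 down with the library term. P53 response camera adjusted p was 0.119 without 1 uM B and 0.0592 without 10 uM A. Of 54 G2 and M phase genes, 0 rose and 0 fell (the same adjusted over the list alone). Their median log2 change was -0.26 (camera adjusted p = 2.29e-07, adjusted p = 0.208 with an estimated correlation). G2 and M phase counts were 0 up and 26 down with the library term. Among 14 Notch pathway genes, 0 rose and 0 fell (0 and 1 adjusted over the list alone, namely HES4 at -0.60 ± 0.13 and adjusted p = 0.0383). At a median log2 change of -0.27, the camera adjusted p was 0.0129, and an adjusted p = 0.175 with an estimated correlation. Notch pathway counts were 2 up and 5 down with the library term. Notch pathway camera adjusted p was 0.0555 with no low-count filter, 0.105 without 1 uM A and 0.0514 without 10 uM A. Of the 11 Hedgehog pathway genes, 0 rose and 0 fell (the same adjusted over the list alone). By camera, the list's adjusted p was 0.00895, and the adjusted p = 0.168 with an estimated correlation, and 0.0783 with the library term, at a median log2 change of -0.23. Hedgehog pathway counts were 1 up and 2 down with the library term. Hedgehog pathway camera adjusted p was 0.116 without 1 uM B. By fry, which tests a list against no change, the adjusted p was 0.0626. None of the 25 anchors passed (adjusted p 0.0906 to 1). With the library term, DHRS3 (1.79e-14) and GATA4 (0.0146) were among those that passed, and PAX9, PAX1, FGF8, HHEX, FOXA2 and EPCAM were not (0.160 to 0.67). The other 23 lists had camera adjusted p-values from 0.0539 to 0.980, of which pharyngeal endoderm factors (0.167) had 0.0403 with the library term. Median, mean and direction of the test differed in sign for the mesoderm genes, FGF pathway genes and BMP pathway genes.

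**Figure D3:**
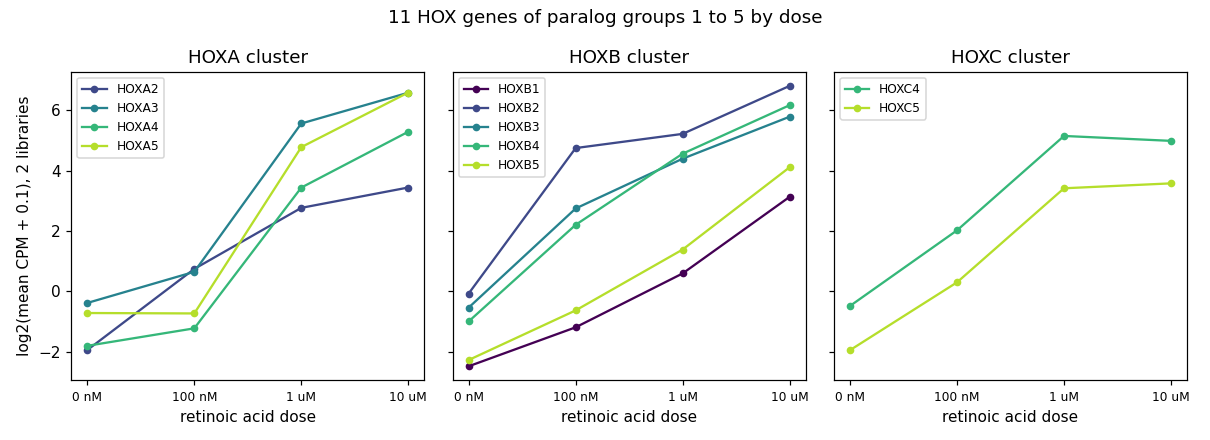
Mean expression of 11 HOX genes of groups 1 to 5, as log2 of mean CPM + 0.1 over 2 libraries, against retinoic acid dose, with one panel each for the HOXA, HOXB and HOXC clusters and one line per gene. HOXA5 lies at 0.510, 0.504, 27.2 and 95.6 CPM from the lowest to the highest dose.

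Over all 4 doses, 5149 genes differed between any doses (edgeR, adjusted p), 13879 with the library term and 3292 with the filter of 10 CPM in 2 sums. Of the 5149, 1615 had their highest mean at 0 nM (31.4%), 1025 at 100 nM (19.9%), 894 at 1 uM (17.4%) and 1615 at 10 uM (31.4%). PAX9 and PAX1 had theirs at 100 nM, OTX2 and FGF8 at 0 nM, GABRB2 and FRZB at 1 uM, and DHRS3 and HOXA3 at 10 uM.

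**Figure D4:**
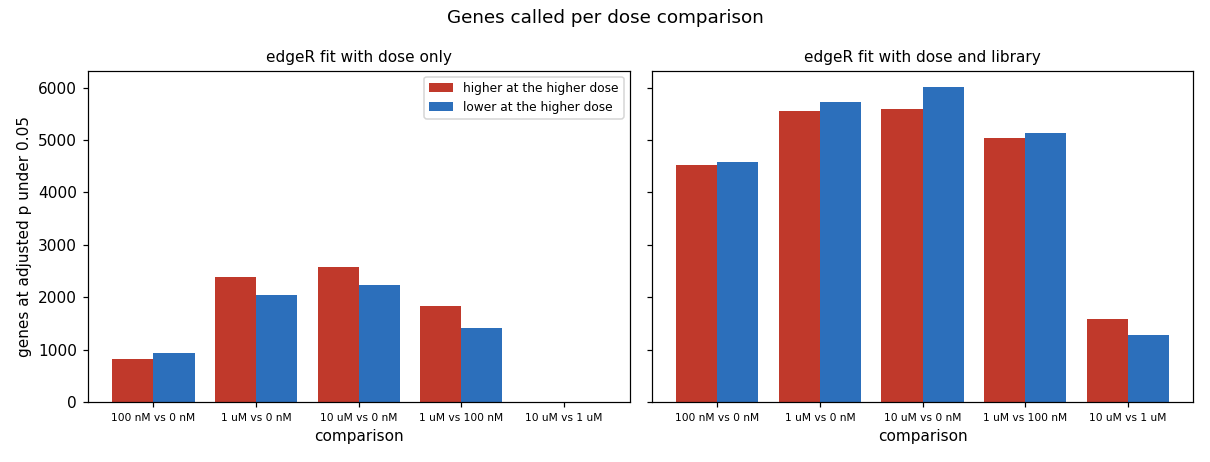
Numbers of genes at an adjusted p under 0.05 (vertical axis) in each of the 5 dose comparisons, as bars for genes higher and lower at the higher dose, with dose alone in the model on the left and dose and library on the right. For 10 uM against 1 uM, the bars stand at 0 and 0 on the left and at 1589 and 1289 on the right.

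Cell cycle phase was called per cell from S and G2/M gene scores after thinning to 5000 UMIs, and shares are means ± SD (n = 2) at 0 nM, 100 nM, 1 uM and 10 uM. Cells called G2 or M made up 17.3% ± 1.56, 40.6% ± 2.46, 27.7% ± 2.39 and 23.4% ± 0.162, cells called S 40.8% ± 1.54, 39.3% ± 2.31, 13.2% ± 2.25 and 15.8% ± 0.590 and cells called G1 41.9% ± 0.0216, 20.03% ± 0.158, 59.2% ± 0.139 and 60.8% ± 0.751. Without thinning, the G2 or M shares were 15.8%, 40.4%, 26.1% and 23.2%, the S shares 41.4%, 39.1%, 13.8% and 15.9% and the G1 shares 42.7%, 20.4%, 60.0% and 60.9%. The S share had a Spearman rho with dose of -0.732 over the 8 sums (exact permutation p = 0.0660 with doses permuted within library, two-sided, where 0.00347 is the smallest possible), and the G2 or M share a rho of 0.195 (exact permutation p = 0.698). Thinning left out 36, 67, 51 and 33 cells in A and 57, 106, 41 and 56 in B. Free RNA in the droplets, which the doses of a library share, also enters the scores and was not measured, so no change in cycling is read from the phase calls alone.

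Shares of cells with a UMI of a gene rise with its CPM, so spread over cells was not tested. Median depths before thinning were 13503 to 18048 UMIs per cell. Thinned to 5000 UMIs, MEIS2, a HOX cofactor, was seen in 10.4%, 51.2%, 59.3% and 59.6% of cells at 0 nM, 100 nM, 1 uM and 10 uM (28.7%, 80.5%, 84.8% and 86.4% without thinning). HOXA3 was seen in 0.158%, 0.705%, 21.8% and 37.2% (1.25%, 2.54%, 48.8% and 71.5% unthinned), and CYP26A1 in 41.6%, 12.1%, 66.1% and 91.3% (65.2%, 25.4%, 83.5% and 94.6% unthinned). PAX9 was seen in 0.156%, 8.84%, 0.0906% and 0.0783% (0.845%, 27.2%, 0.218% and 0.411% unthinned) and PAX1 in 0.573%, 8.60%, 0.0906% and 0.291% (1.55%, 21.9%, 0.151% and 0.487% unthinned). OTX2 was seen in 68.8%, 46.2%, 4.31% and 3.11% (90.4%, 76.3%, 15.2% and 11.7% unthinned). The doses of a library shared 1 pool of droplets, so the lowest share among the doses bounds what free RNA adds, as for PAX9 at 1 uM and 10 uM or HOXA3 at 0 nM. Of the 25 anchors, 23 had their highest share at the dose of their highest CPM.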

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

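The tests of transcript length, of GC content over called genes, of the 100 nM genes under the strict cell filter and of these genes in the other library were chosen only after the result was seen.

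Signal appeared in data outside the comparisons. Hashtags of the other 3 doses made up 6.39%, 3.96%, 2.49% and 3.16% of hashtag counts at 0 nM, 100 nM, 1 uM and 10 uM in A, and 6.09%, 4.14%, 3.33% and 4.22% in B, above the limit that 0 counts allow. In 1 cell (A, 0 nM), another dose's hashtag was the highest. Barcodes under 500 genes, which the sums leave out, made up 11%, 7.88% and 5.87% at 100 nM, 1 uM and 10 uM in A (5.10% at 0 nM) and 8.14%, 4.97% and 5.44% in B (1.62% at 0 nM).

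Libraries A and B differed in 10601 genes with dose in the model, 4930 higher in B and 5671 in A, and 72 of 80 ribosomal protein genes were higher in B (median log2 2.09, 19.0% of UMIs against 9.80%). The tables argue against low-depth cells, since the strict filter left the changes at a slope of 1.001 with 10587 genes called. For transcript length, Spearman rho was -0.048 without ribosomal protein and mitochondrial genes, which lies within the bound set against it. Over all genes called it was -0.104, just outside that bound, so transcript length stays open. GC content also stays open, because its values (0.251 and 0.295) lie between the bounds set for and against it. No biological explanation was tested, since the labels do not say whether A and B were separate cultures.

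Genes higher at 100 nM than at both 0 nM and 1 uM, such as PAX9, PAX1, SMIM32 and FOXI3, numbered 273, where 833 rises and 1419 falls among 17191 genes give 68.8 if independent. The other orders also exceeded independence (207 rising at both steps against 89.4, 199 falling at both against 77.01, 208 falling then rising against 100.1). With the library term, 1942 genes rose then fell against 1349 if independent, 1512 fell then rose against 1339.8, 1316 rose at both steps against 1324 and 1399 fell at both against 1366. Part of the excess may come from the 100 nM libraries that both comparisons share. A covariance test across separate libraries, set beforehand, came out at -0.0212 on average (-0.0591 over all libraries, -0.0298 simulated) and by its bound counted for chance, but genes rising or falling at both steps offset it, so it does not decide. Of genes at least 2-fold higher at 100 nM in 1 library, 130 of 130 and 122 of 122 were higher in the other. All genes at 5 CPM gave 28.4% and 29.9%, which argues against chance in single libraries. The strict filter kept a median 1.002 of the change, which argues against low-depth cells. Left are a dose response and culture differences A and B may share, from 1 experiment with 2 libraries.

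Between 1 uM and 10 uM, dose alone called 0 genes (edgeR, 1146 at an unadjusted p under 0.05, 197 by DESeq2), and 2878 were called with the library term. Against chance in single libraries, log2 changes in A and B correlated over all genes with r = 0.454. The strict filter gave 2838 calls with the library term (3 residual degrees of freedom), which argues against low-depth cells. Left are a response to the higher dose and culture differences A and B may share.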

How the results depend on the processing

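Removing the highest doublet scores, leaving out low-depth and mesoderm-like clusters, and combining the library term with a 2-fold minimum or an estimated correlation were chosen only after the result was seen. The planned shares of cell classes and the selection of an endoderm class were not run, since no cluster of 0 nM cells met the fixed naming rule.

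With the library as replicate block, genes called rose to 9101 for 100 nM against 0 nM, 11264 for 1 uM, 11609 for 10 uM, 10159 for 1 uM against 100 nM, 2878 for 10 uM against 1 uM and 13879 for any dose, since this term takes the difference between A and B out of the spread (common dispersion 0.0686 without it and 5.09e-04 with it). For 10 uM against 1 uM, where dose alone called 0, DESeq2 called 197, no low-count filter 26, equal cells per sum 6 and the library term with a 2-fold minimum 398. Library totals called 1031 genes at 100 nM against 0 nM (1766 with TMM), and the cause was not tested. At least 10 CPM in 2 sums gave 2957 for 1 uM, 3137 for 10 uM and 3292 for any dose, with fewer genes tested. All other settings but leaving out a sum stayed within 1.5 times the count.

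Leaving out 1 sum gave 569 to 1281 genes for 100 nM against 0 nM, 2627 to 3863 for 1 uM, 3005 to 4264 for 10 uM and 1675 to 2781 for 1 uM against 100 nM, 0 in every case for 10 uM against 1 uM, and 3488 to 3921 for any dose; the lone sum of a dose is assumed to vary like the others, and 1 residual degree of freedom is lost. Of 60 called list tests, 0 were called with an estimated correlation, with or without the library term, against 98 of 155 by fry, and the library term ended 10. No called list test changed direction.

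Of 613 called changes of named genes, such as PAX9 and HOXA3, 0 changed sign in any setting. Leaving out a sum, taken over all sums, ended more of these calls than any other setting. Library totals ended 106 and the library term 0. Of 59 changes of anchors not called, 13 changed sign. Of 200 shares of cells with a UMI, 180 unthinned and 158 at 2500 UMIs lay outside the 95% interval at 5000. Depth thus sets their size. For 23 of 25 anchors unthinned and 20 at 2500 UMIs, the highest share and highest CPM fell at the same dose. Depth limits genes of 0 counts at a dose to a bound and those of 1 to 3 counts to an interval.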

Other observations

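The test of HOX paralog number below was chosen only after the result was seen, as were the genes named here.

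Some genes with large changes between 1 uM and 10 uM passed with the library term but not with dose alone. CFAP126, which encodes a protein of the cilium base, stood at 19.5 ± 8.61 CPM at 1 uM and 98.3 ± 47.0 CPM at 10 uM (mean ± SD, n = 2; log2 2.33 ± 0.07 and adjusted p = 5.57e-27 by edgeR with the library term, 0.186 without). TCTEX1D1, a dynein light chain relative, had 2.38 ± 0.10 (3.72e-22 with the library term, 0.0694 without), and EFCAB1, a calcium-binding ciliary protein, had 2.01 ± 0.14 (1.22e-15 and 0.0723). PALMD had 2.80 ± 0.15 (5.62e-19 and 0.0906), CDKN2B, a cell cycle inhibitor, 2.16 ± 0.10 (7.29e-21 and 0.0906), and AGT, angiotensinogen, 1.81 ± 0.08 (2.78e-21 and 0.0694). FRMD4A had -1.93 ± 0.11 (2.68e-18 and 0.0723), LYPD6B -1.43 ± 0.07 (9.81e-20 and 0.0694) and RGS2 -1.14 ± 0.05 (1.72e-20 and 0.135).

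Some genes turned between the dose steps. COL25A1, a collagen of neuromuscular development, stood at 2.14 ± 0.266, 37.4 ± 7.03, 1.17 ± 0.527 and 0.980 ± 0.0556 CPM at 0 nM, 100 nM, 1 uM and 10 uM, while BMP3 stood at 10.4 ± 4.36, 0.427 ± 0.00458, 45.3 ± 13.7 and 30.0 ± 7.34 and GFRA1, a GDNF receptor, at 53.9 ± 3.77, 4.44 ± 1.02, 75.0 ± 10.1 and 110.4 ± 14.0.

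HOX genes of higher paralog number, which lie later in each cluster, were tested for a larger change between 1 uM and 10 uM. Over 12 genes, paralog number and log2 change had a Spearman rho of 0.128 (permutation p = 0.345, one-sided, 100000 permutations), 0.185 in A and 0.0606 in B. HOXA5 had 1.81 and HOXB5 2.77, but HOXB1 had 2.54 and HOXC5 0.16. The 95% bootstrap interval of rho over genes, -0.568 to 0.825, holds the bounds set for and against the hypothesis, so the test does not decide.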
